A study of Mus musculus with 6 samples.

How the data were processed

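The study measured total RNA from cultured mouse lung fibroblasts on single-colour Affymetrix arrays, with 100 ng of RNA per labelling reaction, per the labels' protocols. RNA was primed with an oligo(T) primer carrying a T7 promoter, amplified by in vitro transcription and biotinylated. The deposited value table holds log2 expression per probe set for 6 arrays. The submitters' processing notes name oligo, RMA and limma, with no versions. RMA corrects the background, equalizes the distributions of the arrays by quantile normalization and summarizes the probes of a probe set on the log2 scale, and the values of the deposited table have the range and the near-equal quartiles that this gives. RMA assumes that most genes have like distributions on all arrays, so a shift of all genes in one direction would be removed, and fold changes of dim probe sets are compressed. Detection calls were not used here. The genome build is not given in the sources used here, and no coordinates are printed.

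Arrays were grouped by the treatment in their labels into vehicle (n = 3) and 1 µg/ml 4OHT for 48 h (n = 3). Of 41345 probe sets, 23521 had 1 gene symbol in the platform's annotation, 1814 had several and 16010 had none. Only probe sets with 1 symbol were tested. 23328 of them matched the RefSeq gene table of the GRCm38.p6 assembly by gene number, which was used for names alone and changed no symbol. Where several probe sets named a gene, the one with the highest mean over all arrays represented it, which left 22180 genes. 1082 genes had more than 1 probe set, and in 443 of these the probe sets differed in the sign of the fold change, but none of the 6 such genes among those named did so. No filter was set on dim genes.

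Groups were compared in R 4.3.3 with limma 3.58.1, with lmFit and eBayes on the log2 values with no trend and no robust estimate, as two-sided tests. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. The moderated test had 6.70 degrees of freedom. Log2 fold changes are 4OHT minus vehicle. A log2 fold change is given as its value, or as its size after "fell by" or "rose by".

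The text names genes by a rule. It takes Gli1, Ptch1, Hhip, Smo, Gli2 and Gli3 always, and 1 further gene set for the hedgehog check is not reported here. It then takes the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups do not overlap, leaving out predicted, microRNA, small nucleolar RNA, olfactory and vomeronasal receptor genes. From each gene list it takes up to 4 members of smallest p. The rule gave 137 genes. 29 gene lists were written from textbook knowledge of lung fibroblasts, hedgehog signalling, tamoxifen compounds and the activity of Cre recombinase. They held 819 different symbols, of which 765 were measured. They covered hedgehog targets and components, the primary cilium, the cell cycle, matrix, contractile, lipid, growth factor, signalling, stress and immune genes, and markers of the cell types of the lung. The groups, tests, lists, naming rule and alternatives, with the exception named below, were fixed before the data were examined.

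Lists were compared with other genes by limma's camera with its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists. 17 lists passed, 4 higher and 13 lower. With the correlation estimated for each list none passed, and by fry, which tests whether the members of a list move one way on balance, 21 did. An exact two-sided permutation test was used for the mean of Gli1, Ptch1 and Hhip.

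The alternatives were the replicate number as a block, centring the arrays on their medians, a second quantile normalization, only genes above the median level, the mean of a gene's probe sets, a trended and robust eBayes, array weights, stricter thresholds, a fit over all probe sets, and leaving out each array in turn. Leaving out list members that stand in several lists was added after seeing the data. The tests were tried on simulated data with the same number of genes and arrays and 200 changed genes. They recovered 11.9% of genes changed 1.2-fold, 90.4% of those changed 1.5-fold and 99.4% of those changed 2-fold. No sign was wrong, and 5.89% of calls were false. In the real comparison 2662 genes were called, and the adjustment depends on how many genes change, so these shares need not hold there. A simulated list of 30 genes shifted by 0.3 on the log2 scale was called in 20 of 20 runs, and 1 of 560 lists with no shift was called. The simulated genes varied independently of each other, whereas the correlation estimated for the interferon-stimulated list was 0.46. These runs therefore cannot show how often camera calls a list of genes that move together.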

Results

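Gene expression was measured on arrays in primary fibroblasts grown from the lungs of adult mice. The mice carried an inducible allele of SmoM2, a constitutively active form of Smoothened, the membrane protein that switches on hedgehog signalling. 3 wells received vehicle and 3 wells received 1 µg/ml 4-hydroxytamoxifen (4OHT), the active metabolite of tamoxifen, and RNA was taken after 48 h, which gave 6 arrays. The labels describe wells split from isolated cells and give every array the same genotype number, and nothing in them says that the wells came from separate animals. The p-values therefore measure only the spread between wells, which may be technical. Every array came from cells with the SmoM2 allele, so the drug, the induction of the allele and the activated allele differ together between the groups. The number of arrays limits the precision of every value below.

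The arrays were alike within a group. Pearson's r over the 22180 genes lay between 0.997 and 0.998 for arrays of a group and between 0.995 and 0.996 for arrays of different groups, across genes, which are not independent replicates. Median log2 expression ranged from 7.44 to 7.47, and no array repeated another. The first principal component held 54.4% of the variance and placed the vehicle arrays between -15.6 and -15.0 and the 4OHT arrays between 11.8 and 17.7.

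The first comparison asked whether 4OHT turned on the direct target genes of hedgehog signalling. Gli1, the transcription factor most widely used as a readout of the pathway, rose 1.28-fold, from a log2 expression of 6.46 ± 0.03 in vehicle wells to 6.81 ± 0.11 in 4OHT wells (SD, n = 3; log2 fold change 0.35, SE 0.064, adjusted p = 0.0167). Ptch1, the hedgehog receptor and itself a target, had a log2 fold change of 0.08 (95% interval -0.07 to 0.24, adjusted p = 0.485). Hhip, a hedgehog-binding antagonist induced by the pathway, had a log2 fold change of 0.05 (95% interval -0.20 to 0.31, adjusted p = 0.803). The mean log2 expression of Gli1, Ptch1 and Hhip was 7.25 ± 0.05 in vehicle wells and 7.42 ± 0.05 in 4OHT wells (SD, n = 3), and an exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 can give. The Gli1 call did not hold without vehicle replicate 1 (adjusted p = 0.0538), vehicle replicate 2 (0.0541) or vehicle replicate 3 (0.0543). It held without any of the 4OHT arrays and was lost with the replicate number as a block (adjusted p = 0.0560).

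Other genes of the pathway were level or lower. Gli2, the main activating transcription factor of the pathway, fell by 0.19 on the log2 scale (SE 0.042, adjusted p = 0.0295), a call that was lost without any of the 6 arrays (adjusted p from 0.0707 without 4OHT replicate 3 to 0.101 without vehicle replicate 2). Smo had a log2 fold change of -0.10 (adjusted p = 0.204) and Gli3 of 0.01 (adjusted p = 0.920). Nothing in the sources says whether the Smo probe set reads the SmoM2 transcript. Among 28 measured genes of a list of hedgehog targets, 1 was higher, 7 were lower and 20 did not pass; adjusted over the list alone, 3 were higher and 9 lower. Sfrp1, a secreted Wnt inhibitor, fell by 0.67 on the log2 scale, Rasl11b by 0.69, the growth factor gene Igf2 by 0.49 and the transcription factor gene Foxc2 by 0.38. The list had a median log2 fold change of -0.09 and lay lower than other genes by camera (adjusted p = 0.0490; adjusted p = 0.410 with an estimated correlation). That call was also lost without vehicle replicate 2 (adjusted p = 0.0602), vehicle replicate 3 (0.0707) or 4OHT replicate 2 (0.119), with quantile normalization applied again (0.0528), and, in an alternative chosen after seeing the data, without members that other lists hold (0.287); without vehicle replicate 2, vehicle replicate 3, 4OHT replicate 1 or 4OHT replicate 2, 4 members were lower. Of 25 measured pathway components, 4 were lower and none higher (adjusted over the list alone, 6 lower and 2 higher), and the list did not pass by camera (median log2 fold change -0.05, adjusted p = 0.133; adjusted p = 0.0193 lower with fry). Boc, a hedgehog co-receptor, was among those lower (log2 fold change -0.26, adjusted p = 0.0132), a call lost without 4OHT replicate 1 (adjusted p = 0.0524). Between 1 and 2 of the components were lower when any of the 6 arrays was left out.

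Genes of the primary cilium, the organelle in which Smoothened acts, were mostly level. 3 of 29 measured cilium genes, Bbs7, Rpgrip1l and Dync2h1, were higher by 0.25 to 0.38 on the log2 scale and none was lower, with the same counts adjusted over the list alone. The list had a median log2 fold change of 0.01 (adjusted p = 0.104). Each of the 3 calls was lost without vehicle replicate 1, vehicle replicate 2, 4OHT replicate 1 or 4OHT replicate 2, and the list passed without vehicle replicate 3 (adjusted p = 0.0263).

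**Figure D1:**
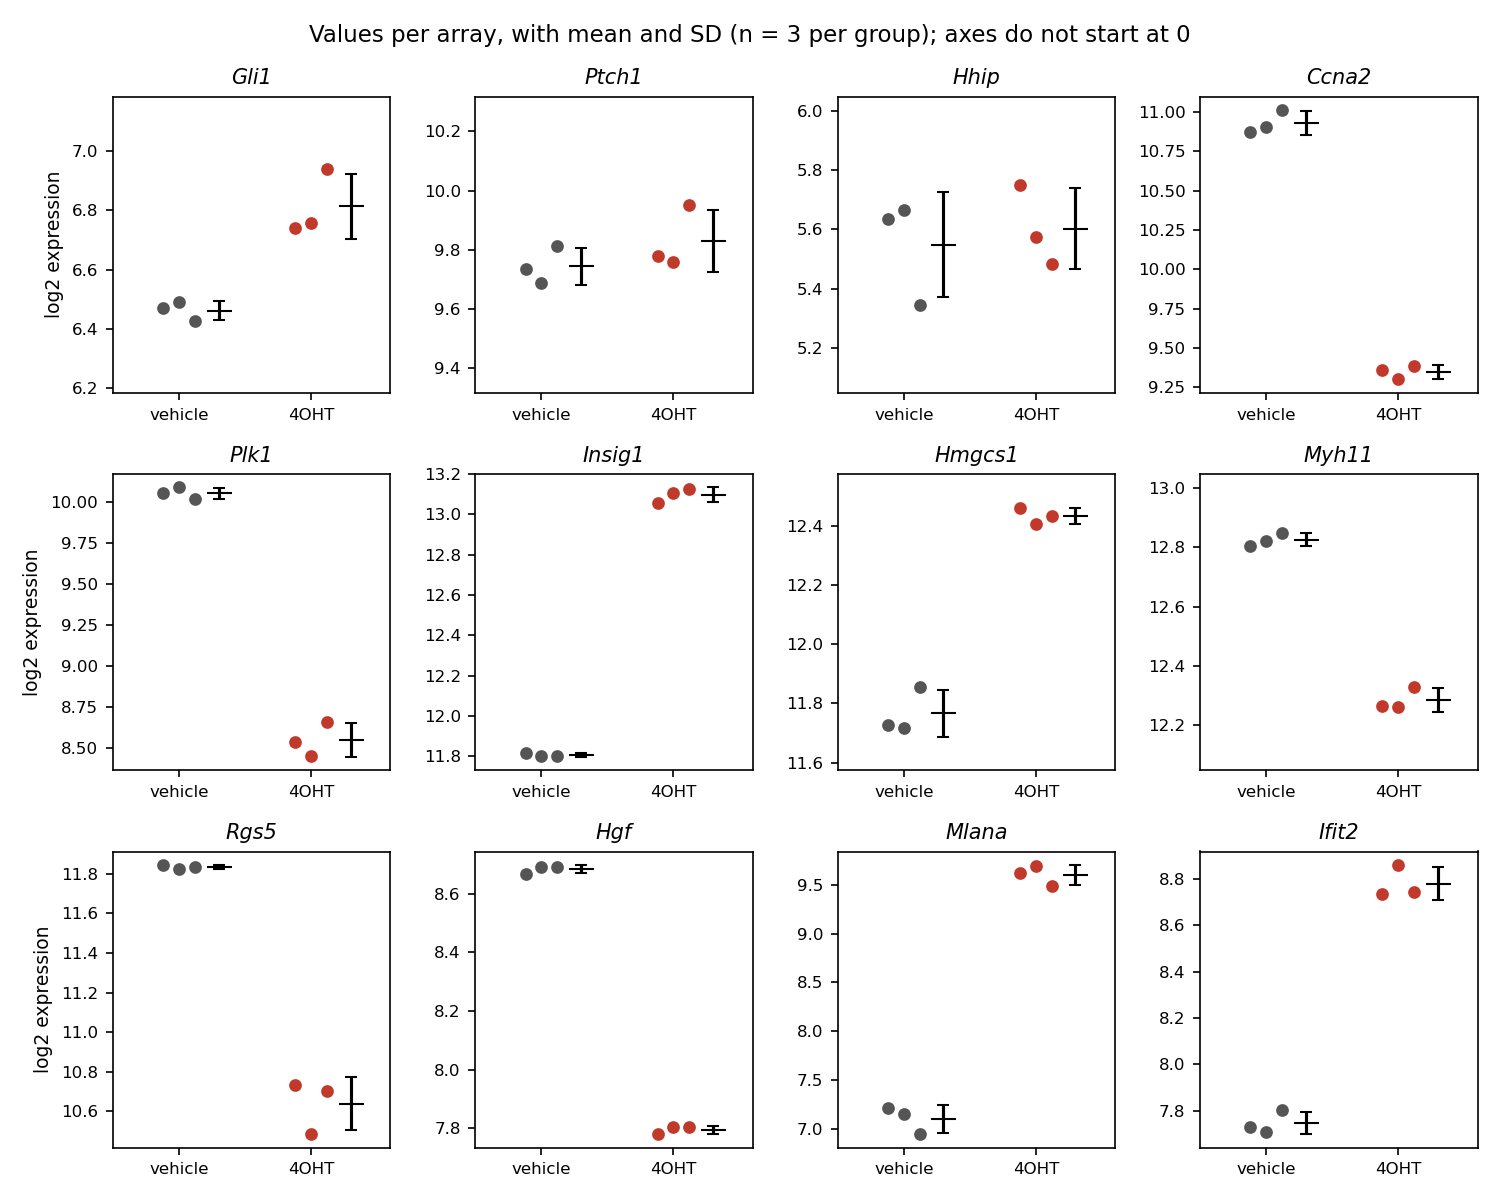
Log2 expression of 12 genes on each array, with a panel per gene; points are arrays (grey, vehicle; red, 4OHT) and the bars beside them show the mean and SD (n = 3 per group). Gli1 lay between 6.43 and 6.49 on the vehicle arrays and between 6.74 and 6.94 on the 4OHT arrays, while the values of Ptch1 and Hhip overlapped between the groups.

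The second comparison covered all genes. 2662 of 22180 genes passed an adjusted p under 0.05, 1193 of them higher and 1469 lower in 4OHT wells, and their median absolute log2 fold change was 0.34. Changes of at least 2-fold were found for 25 genes that rose and 78 that fell. Among genes with names other than those of predicted or small RNA genes, the largest rise was that of Mlana, a melanosome protein, at 5.66-fold, from a log2 expression of 7.10 ± 0.14 to 9.60 ± 0.10 (SD, n = 3; adjusted p = 0.000114). It was followed by Rragd (3.65-fold), a GTPase that helps place mTORC1 on lysosomes, the proton channel gene Hvcn1 (3.57-fold) and Gpnmb (3.51-fold), which encodes a glycoprotein of lysosomes and melanosomes. Mmp3 and Mmp8, which encode secreted matrix metalloproteinases, rose 3.24-fold and 2.78-fold. Chchd10, a mitochondrial protein gene, rose 2.98-fold, the matrix glycoprotein gene Tnxb 2.75-fold and the kinesin gene Kif1a 2.72-fold. Star, whose product carries cholesterol into mitochondria, rose 2.55-fold, and Tppp3 and the retinoic acid binding protein gene Crabp2 rose 2.54-fold and 2.52-fold.

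The largest fall was that of Lrrc17, at 3.49-fold lower (log2 fold change -1.80, SE 0.12, adjusted p = 0.000463). Col10a1, a collagen gene, was 3.21-fold lower, Sfrp2, a secreted Wnt modulator, 3.16-fold lower and the collectin gene Colec11 3.02-fold lower. Ccna2, which encodes cyclin A2, was 2.99-fold lower. Further genes of cell division followed, with Plk1 at 2.84-fold, Ndc80 at 2.83-fold, Kif11 at 2.78-fold and Nusap1 at 2.76-fold lower. Susd2, Prr11 and Prss35 were 2.92-fold, 2.87-fold and 2.87-fold lower. In 7256 genes (32.7%) the 3 values of 1 group all lay beyond the 3 of the other, against 10% by chance. This held for all 2662 genes called, which were picked by a test on the same values. The count of genes called was 1585 without vehicle replicate 1, 1336 without vehicle replicate 2, 1473 without 4OHT replicate 1 and 1220 without 4OHT replicate 2. It was 4123 with a trended and robust estimate of the spread, and with the arrays centred on their medians more genes were higher (1406) than lower (1288).

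**Figure D2:**
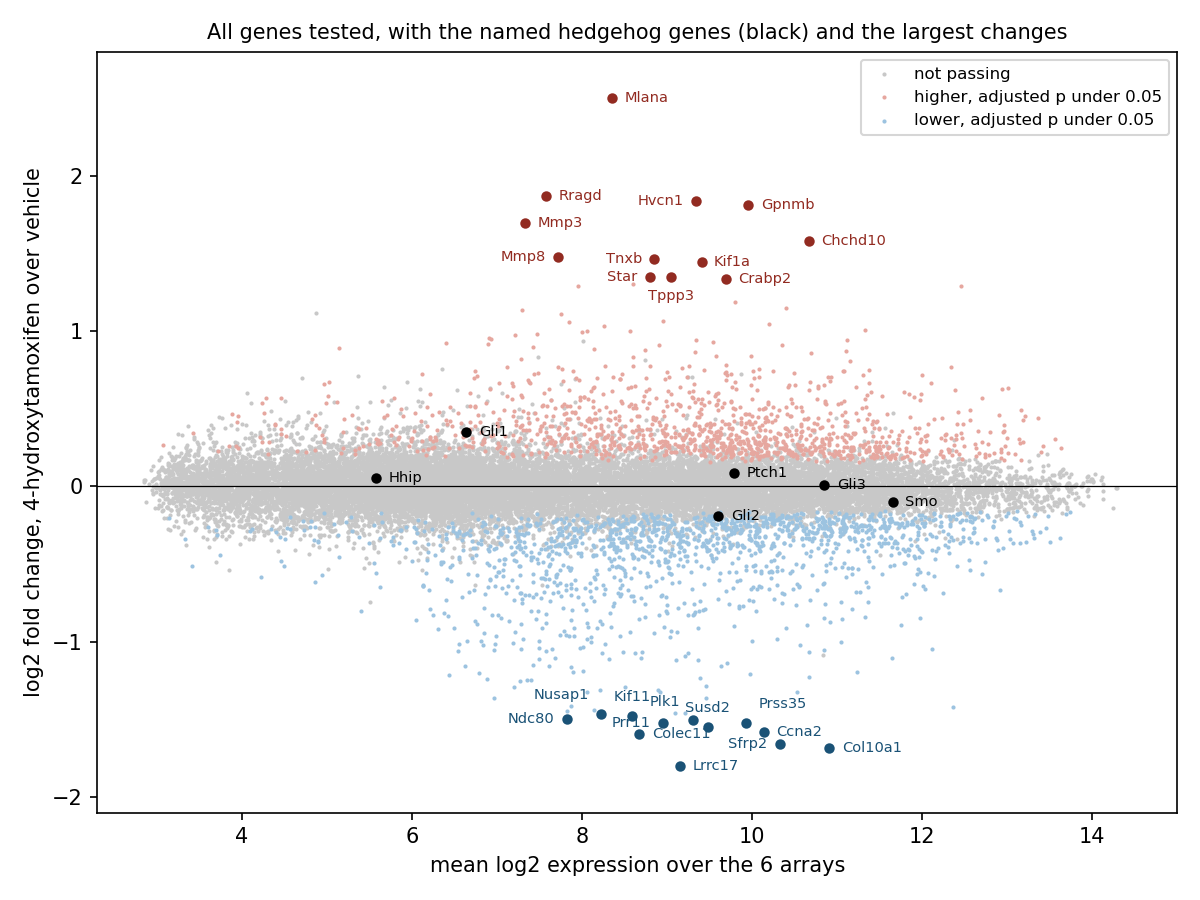
Log2 fold change of 4OHT over vehicle against mean log2 expression over the 6 arrays for the 22180 genes, each point a gene, coloured by whether it passed an adjusted p under 0.05. The hedgehog genes Gli1, Ptch1, Hhip, Smo, Gli2 and Gli3 (black) lie between -0.19 and 0.35. The 12 largest rises start at 1.33 for Crabp2, and the largest fall reaches -1.80.

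Genes of cell division were lower in 4OHT wells. In the list of G2/M and mitosis genes, 59 of 65 measured members fell and none rose; adjusted over the list alone, 63 fell. The median log2 fold change was -0.94, or 1.92-fold lower. Plk1, a mitotic kinase, fell by 1.51 on the log2 scale, Prc1 and Anln, which act in cytokinesis, by 1.46 and 1.21, and the kinetochore gene Nuf2 by 1.44. The list passed by camera (adjusted p = 7.7e-48; adjusted p = 0.0973 with an estimated correlation). Of 41 measured genes of the G1/S transition and DNA replication, 25 fell and none rose (29 adjusted over the list alone), with a median log2 fold change of -0.40. Ccna2 fell by 1.58 on the log2 scale, Mcm5, a subunit of the replicative helicase, by 1.31, and Dtl, which acts in replication licensing, by 1.06. Camera gave an adjusted p of 8.4e-18 for this list (adjusted p = 0.0973 with an estimated correlation). An estimated correlation gave the highest adjusted p of all alternatives for every list called here.

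Cell cycle inhibitors and regulators of quiescence went both ways. 2 of 23 measured members were higher and 5 lower (3 and 6 adjusted over the list alone). Klf4, a transcription factor gene, rose 2.07-fold, while Btg1, an antiproliferative gene, fell by 0.48 on the log2 scale, Txnip by 0.35 and Gas2 by 0.42. The list did not pass (adjusted p = 0.825), and its median log2 fold change of 0.04 differed in sign from its mean of -0.0044 and from the direction of the test. Without vehicle replicate 1 or 2 or 4OHT replicate 1 or 2, 1 member was higher, and without 4OHT replicate 2, 3 were lower.

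Cholesterol biosynthesis genes were higher together. All 19 measured members passed in the direction of a rise, as they did adjusted over the list alone, and between 15 and 19 did so when any of the 6 arrays was left out, with a median log2 fold change of 0.51, or 1.42-fold. Insig1, a sterol-regulated gene that restrains the pathway, rose 2.45-fold, from a log2 expression of 11.81 ± 0.01 to 13.10 ± 0.04 (SD, n = 3). Lss, which encodes lanosterol synthase, rose 1.81-fold, and Hmgcs1, which encodes the synthase of the precursor HMG-CoA, rose 1.59-fold. Msmo1, a sterol demethylation gene, rose by 0.67 on the log2 scale. Camera gave an adjusted p of 2.4e-20 (adjusted p = 0.0973 with an estimated correlation). In the list of lipofibroblast and adipogenic genes, 5 of 23 measured members were higher and 3 lower (5 and 4 adjusted over the list alone). The fatty acid synthesis genes Acaca and Fasn rose 1.88-fold and 1.70-fold and the desaturase gene Scd1 by 0.63 on the log2 scale, while Angptl4, a lipase inhibitor gene, was 2.44-fold lower. This list did not pass (median log2 fold change 0.09, adjusted p = 0.0766). It passed with fry (adjusted p = 0.0128), without 4OHT replicate 2 (adjusted p = 0.0328, with 4 higher and 1 lower), with quantile normalization applied again (0.0491) and, in an alternative chosen after seeing the data, without members that other lists hold (0.0347).

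Contractile genes and markers of smooth muscle and pericytes were lower. Of 26 measured contractile and myofibroblast genes, 16 fell and none rose (23 adjusted over the list alone), with a median log2 fold change of -0.24. Myh11, the smooth muscle myosin heavy chain gene, fell by 0.54 on the log2 scale, Lmod1 by 0.66, the tropomyosin gene Tpm2 by 0.62 and the smoothelin gene Smtn by 0.45. Camera gave an adjusted p of 1.1e-12 (adjusted p = 0.0973 with an estimated correlation), and 10 members were lower without vehicle replicate 1, vehicle replicate 2 or 4OHT replicate 2. Of 18 markers of smooth muscle and pericytes, 13 fell and none rose, and 13 were lower and 1 higher adjusted over the list alone. Rgs5, a pericyte marker, was 2.29-fold lower, the cation channel gene Trpc6 2.37-fold lower and the Notch receptor gene Notch3 fell by 0.55 on the log2 scale. The median log2 fold change was -0.46 (camera adjusted p = 4.0e-09; adjusted p = 0.0973 with an estimated correlation). 9 of the 18 markers stand in another list as well, so the lists do not give independent results.

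Extracellular matrix genes and secreted growth factors were lower on balance. Of 50 measured matrix genes, 20 fell and 2 rose (27 and 4 adjusted over the list alone). Col6a2, a collagen VI chain gene, fell by 0.49 on the log2 scale, the basement membrane gene Nid2 by 0.51 and the proteoglycan gene Fmod by 0.49, while the hyaluronan synthase gene Has1 rose by 0.70. The median log2 fold change was -0.15 (camera adjusted p = 2.8e-07; adjusted p = 0.104 with an estimated correlation), and 13 members were lower without vehicle replicate 1 or 2. Of 44 measured growth factor genes for epithelium and vessels, 17 fell and 1 rose (17 and 2 adjusted over the list alone), with a median log2 fold change of -0.14. Hgf, which encodes hepatocyte growth factor, was 1.85-fold lower, Wnt2b fell by 0.94 on the log2 scale, the Wnt agonist gene Rspo2 by 0.91 and the epidermal growth factor family gene Hbegf by 0.75. Camera gave an adjusted p of 2.6e-05 (adjusted p = 0.156 with an estimated correlation). Matrix proteases and their inhibitors went both ways, with 7 of 27 measured members higher and 7 lower (8 and 8 adjusted over the list alone). Mmp3 and Mmp8 stood among those higher, while the protease genes Adamts1 and Plau fell by 0.69 and 0.58 on the log2 scale. This list did not pass by camera (median log2 fold change 0.02, adjusted p = 0.952; adjusted p = 0.0260 higher with fry), and 4 members were higher without vehicle replicate 2, vehicle replicate 3, 4OHT replicate 1 or 4OHT replicate 2.

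Lists of 3 developmental signalling pathways were lower. Of 23 measured Wnt target and feedback genes, 9 fell and 1 rose (11 and 1 adjusted over the list alone), with a median log2 fold change of -0.13 (camera adjusted p = 6.1e-05; adjusted p = 0.0973 with an estimated correlation). Sfrp2 and Sfrp1, which encode secreted Wnt inhibitors, fell by 1.66 and 0.67 on the log2 scale, the receptor gene Lgr6 by 0.91 and the feedback inhibitor gene Nkd1 by 0.66. Of 25 measured TGF-beta and SMAD target genes, 10 fell and 3 rose (11 and 4 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.0036; adjusted p = 0.0973 with an estimated correlation). Id1, Id2 and Id3, which encode inhibitors of basic helix-loop-helix factors and respond mainly to bone morphogenetic proteins, fell by 0.94, 0.74 and 0.85 on the log2 scale, and the ligand gene Tgfb2 fell by 0.63. The number lower was 6 without vehicle replicate 1, vehicle replicate 2, 4OHT replicate 1 or 4OHT replicate 2. Of 15 measured Notch target genes, 5 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.0080; adjusted p = 0.104 with an estimated correlation). Hey1 and Heyl, transcription factor genes induced by Notch, fell by 1.12 and 0.83, and Dtx4, a ubiquitin ligase gene of the pathway, rose by 0.65.

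Responses that a tamoxifen compound or DNA damage could touch were tested with lists of their own. Of 16 measured estrogen receptor target genes, 5 fell and none rose, with the same counts adjusted over the list alone. Greb1 fell by 0.47 on the log2 scale, the receptor gene Esr1 by 0.37 and the progesterone receptor gene Pgr by 0.35. The median was -0.08 (camera adjusted p = 0.0054; adjusted p = 0.104 with an estimated correlation and 0.0922 among genes above the median level). Of 20 measured genes of the xenobiotic and aryl hydrocarbon response, 4 rose and none fell (5 and none adjusted over the list alone). Hmox1, the heme oxygenase gene, rose by 0.72 on the log2 scale and Txnrd1, a thioredoxin reductase gene, by 0.27. Srxn1 and Slc7a11 rose by 0.28 and 0.26. These were all 4 that rose, so none of the list's cytochrome P450 genes was called over all genes. The list's median was 0.09 (camera adjusted p = 0.0085, or 0.156 with an estimated correlation). 2 of its members were higher without vehicle replicate 1, vehicle replicate 2, 4OHT replicate 1 or 4OHT replicate 2. The p53 and DNA damage list did not pass, with 4 of 26 measured members higher and 2 lower (9 and 2 adjusted over the list alone) and a median of 0.06 (adjusted p = 0.0646). 1 member was higher without vehicle replicate 1, vehicle replicate 2 or 4OHT replicate 2. Trp53inp1, a p53 target, rose by 0.51, and the death receptor gene Fas fell by 0.28, a call lost without 4OHT replicate 2 (adjusted p = 0.0550). That list passed without vehicle replicate 3 (adjusted p = 0.0326) or 4OHT replicate 1 (0.0467), with quantile normalization applied again (0.0251) and, in an alternative chosen after seeing the data, without members that other lists hold (0.0347).

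Stress and immune lists gave a mixed picture. Of 27 measured glycolysis and hypoxia genes, 6 rose and none fell, and 6 were higher and 1 lower adjusted over the list alone. Hk2, a hexokinase gene, rose by 0.57 on the log2 scale, the peptide hormone gene Adm by 0.71 and the mitophagy gene Bnip3 by 0.37, with a median of 0.05 (camera adjusted p = 0.00039; adjusted p = 0.156 with an estimated correlation). In the list of unfolded protein and integrated stress genes, 2 of 28 measured members were higher and 1 lower (3 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.929). Ddit3, which encodes the stress factor CHOP, rose by 0.59, and the disulfide isomerase gene Pdia6 fell by 0.26. The median of this list was -0.02, the mean 0.01, and camera and fry gave opposite directions. Without vehicle replicate 1, vehicle replicate 2 or 4OHT replicate 1, 1 member was higher. Among 41 measured cytokines and chemokines, 10 were lower and 3 higher (13 and 5 adjusted over the list alone). The chemokine genes Ccl2, Ccl7, Cxcl14 and Cx3cl1 fell by 0.79, 0.68, 0.91 and 0.89 on the log2 scale. The list did not pass by camera (median -0.03, adjusted p = 0.123; adjusted p = 0.0096 lower with fry).

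Interferon-stimulated genes were higher on balance, with wide spread among the vehicle wells. Of 30 measured members, 3 rose and none fell, with the same counts adjusted over the list alone. Ifit2, an antiviral effector gene, rose by 1.03 on the log2 scale (adjusted p = 0.000225), Stat2, a transcription factor of the interferon response, by 0.64 and Oas2 by 0.41. The list had a median of 0.34 (camera adjusted p = 0.00023; adjusted p = 0.436 with an estimated correlation and 0.0837 with fry). 23 of the 30 genes were higher in vehicle replicate 1 than in both other vehicle wells, where chance gives 10 on average. These genes move together (estimated correlation 0.46), so by chance too 1 well can hold most of them. This count was chosen after the pattern was seen. Without vehicle replicate 1, 16 members were higher. Without 4OHT replicate 1 or without 4OHT replicate 2, 1 was.

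Markers of fibroblasts and of mesothelium were lower on balance. Of 25 measured fibroblast markers, 4 fell and none rose (8 lower and 1 higher adjusted over the list alone). Cd34 was 1.71-fold lower and Fap, which encodes fibroblast activation protein, 1.53-fold lower, and Dpt and S100a4 fell by 0.56 and 0.42 on the log2 scale. The list's median was -0.07 (camera adjusted p = 0.0357; adjusted p = 0.167 with an estimated correlation). This call was lost without vehicle replicate 2 (adjusted p = 0.0564), vehicle replicate 3 (0.0519) or 4OHT replicate 3 (0.0829), among genes above the median level (0.0966) and, in an alternative chosen after seeing the data, without members that other lists hold (0.0981). Of 13 measured mesothelial markers, 6 fell and 2 rose (7 and 2 adjusted over the list alone), among them Lrrn4, Upk3b and Cldn15, which fell by 0.54, 0.41 and 0.46, with a median of -0.24 (camera adjusted p = 0.0128; adjusted p = 0.119 with an estimated correlation and 0.0852 among genes above the median level).

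The remaining marker lists did not pass by camera. For endothelium, 4 of 20 markers were lower and 2 higher, with the same counts adjusted over the list alone and a median of -0.03 (adjusted p = 0.371; adjusted p = 0.0109 lower with fry). Erg, an endothelial transcription factor gene, was 1.99-fold lower and Cdh5, which encodes VE-cadherin, 1.94-fold lower. Without 4OHT replicate 2, 2 endothelial markers were lower, and 1 was higher without any of the 6 arrays. For macrophages, 3 of 23 markers were lower and 1 higher, again with the same counts adjusted over the list alone and a median of -0.04 (adjusted p = 0.336). The complement gene C1qb was 1.64-fold lower, while Cd68, which encodes a lysosomal membrane protein of macrophages, was 1.40-fold higher. 1 macrophage marker was lower without vehicle replicate 2, vehicle replicate 3, 4OHT replicate 1 or 4OHT replicate 2. For epithelium, 3 of 26 markers were lower and 1 higher, the same adjusted over the list alone, with a median of -0.03 (adjusted p = 0.731). The keratin gene Krt8 fell by 0.33 on the log2 scale, and between 1 and 2 epithelial markers were lower when any of the 6 arrays was left out, with none higher except without 4OHT replicate 3. For lymphocytes and granulocytes, 1 of 20 markers was lower and 1 higher, the same adjusted over the list alone, with a median of -0.03 (adjusted p = 0.952). None of these markers passed in either direction without vehicle replicate 2 or 3, and none was lower without vehicle replicate 1 or 4OHT replicate 2 or 3.

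**Figure D3:**
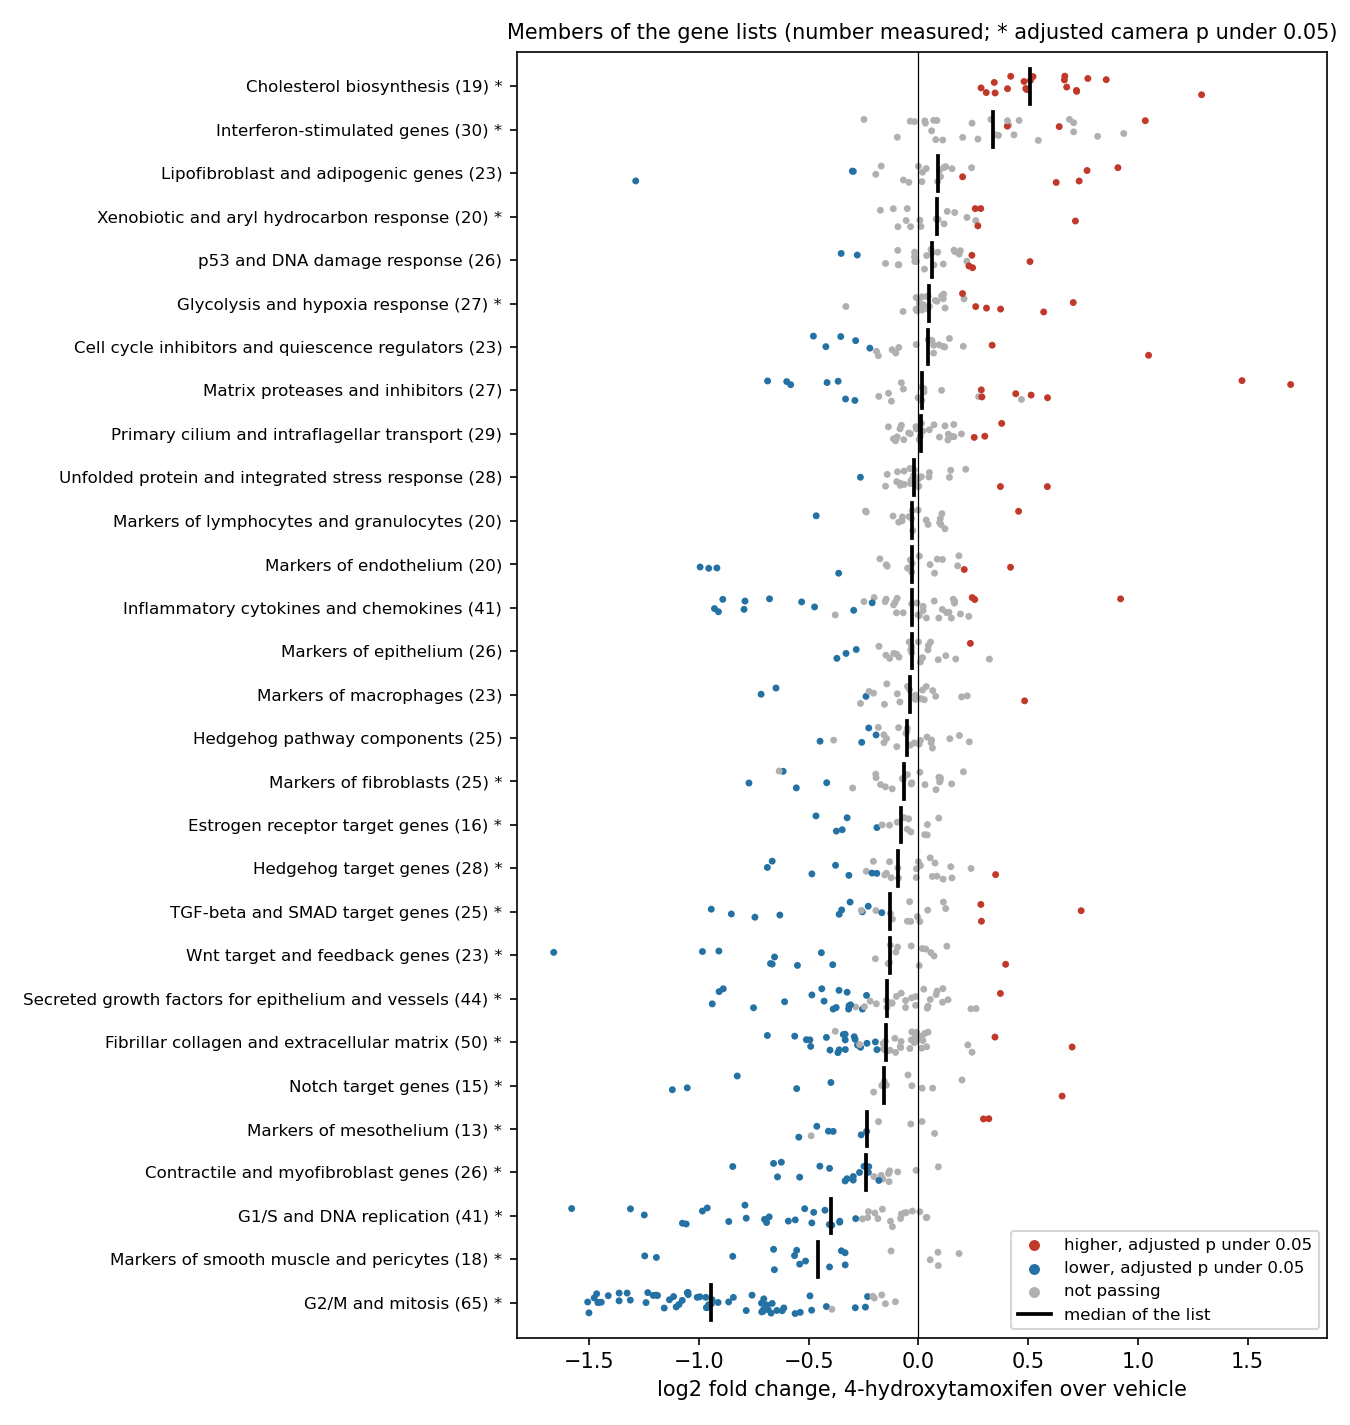
Log2 fold change of 4OHT over vehicle for each measured member of the 29 gene lists, ordered by the list's median (black bar); red and blue points passed an adjusted p under 0.05 and grey points did not. The medians run from -0.94 for G2/M and mitosis to 0.51 for cholesterol biosynthesis, whose 19 members all lie above 0.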

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

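Probe sets outside the gene comparison carried a difference between the groups. 17824 of the 41345 probe sets had no gene name in the annotation or had several, and they entered no comparison of named genes or lists. In a limma fit over all probe sets, 1916 of the 41345 passed an adjusted p under 0.05, 930 higher and 986 lower in 4OHT wells. Of the 17824, 341 were higher and 148 lower (n = 3 per group), together a smaller share than among all probe sets. Most of them had no name, with 309 higher and 104 lower among the 16010 such probe sets. The largest rise was 2.37 and the largest fall -1.96 on the log2 scale. Median log2 expression over all probe sets was 6.695 to 6.717 on the vehicle arrays and 6.725 to 6.776 on the 4OHT arrays. With the arrays centred on these medians, an alternative chosen after seeing the data, 260 were higher and 173 lower. No explanation was tested.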

How the results depend on the processing

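The count of genes called, 2662 with 1193 higher and 1469 lower, moved by over 1.5 times in several settings. With the replicate block it was 1568 (648 higher, 920 lower), with a trended and robust spread 4123 (1828 and 2295), at an adjusted p under 0.01 it was 1010 (395 and 615), and with at least 1.5-fold as well 463 (159 and 304). The stricter thresholds remove genes by construction, and for the others the cause was not tested. Without 1 array it ranged from 1220 to 2326 (486 to 986 higher, 734 to 1340 lower), with fewer arrays in the fit. No gene called both in the report and in an alternative changed sign, but centring the arrays turned the majority, with 1406 genes higher and 1288 lower, a share higher of 52.2% instead of 44.8%.

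Whether the replicate numbers pair the arrays was not settled. The second principal component, with 14.3% of the variance, fell with the number in both groups. It ran from 10.9 to -14.1 on the vehicle arrays and from 4.6 to -4.4 on the 4OHT arrays. The correlations of the deviations of same-numbered arrays were 0.062, -0.024 and 0.043, and 4OHT arrays 1 and 3, but not 2, correlated best with the vehicle array of their own number. Under the replicate block the hedgehog target list kept its median of -0.092 with an adjusted p of 0.0760, with 0 members higher and 4 lower. 16 named genes lost their call there, among them Gli1 (adjusted p = 0.0560), Gli2 (0.0882), Boc (0.0503), Rpgrip1l (0.0661) and Dync2h1 (0.0732).

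With an estimated correlation 0 of the 29 lists passed. The setting changes only the test, so the medians stay as they are. They were -0.092 for hedgehog targets, -0.40 for G1/S, -0.94 for G2/M, -0.15 for matrix, -0.24 for contractile and 0.51 for cholesterol genes. The p-value rose even where the estimated correlation lay below the preset 0.01. For TGF-beta targets, at -0.023, the unadjusted camera p was 0.0235 instead of 0.0014. A higher correlation alone therefore does not account for all the lost calls. The hedgehog target list had a median of -0.073 with quantile normalization applied again and -0.0094 without shared members, an alternative chosen after seeing the data. Without 1 array its median ranged from -0.117 to -0.055. The cause was not tested. Over its alternatives its adjusted p ran from 0.0096 with fry to 0.410.

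The mean of Gli1, Ptch1 and Hhip stayed 0.135 to 0.189 higher in 4OHT in every setting run. Among genes above the median level it has no value, because Gli1 and Hhip lie below that level. Over all settings, the named genes kept their side of the threshold 1641 times, lost it 111 times and gained it 14 times, and the lists other than those named in this part did so 336, 19 and 13 times. For dim genes, signal over the background limits what the arrays can show.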

Other observations

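The lysosomal and liver X receptor lists below were written after the fold changes had first been seen but before the values of any of their members, and their tests were set then. The other tests in this part were chosen after the result was seen, except the counts over other splits of the arrays.

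Lysosomal genes were higher in 4OHT wells. Of 48 measured genes for lysosomal enzymes, membrane proteins and the proton pump, 24 rose and 1, Gm2a, fell (34 and 1 adjusted over the list alone). The chloride transporter gene Clcn7 rose by 0.49 on the log2 scale, the sialidase gene Neu1 by 0.47, and the proton pump genes Atp6ap2 and Atp6v1a by 0.44 and 0.38. Npc1 and Npc2, whose products move cholesterol out of lysosomes, rose by 0.30 and 0.27. Camera gave an unadjusted p of 2.1e-13, or 0.0040 with an estimated correlation, where the unadjusted p was 0.0071 for the G2/M list and 0.0156 for the cholesterol list. The G2/M and cholesterol lists were fixed before the data were examined and the lysosomal list was not, so its p-value does not rank it against them. Of 9 measured liver X receptor target genes, which respond to oxysterols, 3 rose and none fell (5 and 1 adjusted over the list alone). They were the cholesterol exporter gene Abca1, at 0.49, Srebf1, at 0.42, and Lpcat3, at 0.26. In all, 6 of the 9 had a log2 fold change above 0. Mylip (-0.19), Abcg1 (-0.16) and Abcg4 (-0.12) went the other way and did not pass over all genes. Camera gave an unadjusted p of 0.0255 for this list, or 0.0810 with an estimated correlation. These genes were named after their values were seen.

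The rise of all 19 cholesterol synthesis genes may be part of a wider sterol and lysosomal response. A shift that depends only on brightness is argued against, since the middle 95% of the medians of 10000 random lists matched on level ended at 0.0579, against 0.51 for the sterol genes. The lysosomal list had a median log2 fold change of 0.183, above all 10000 matched lists. The liver X receptor list had one of 0.192, above 99.9% of its own, though its bootstrap interval, with its genes resampled, ran from -0.16 to 0.42. Tamoxifen compounds are cationic amphiphilic amines, a class known to gather in lysosomes and to disturb sterol metabolism, so a response to the drug itself is a candidate explanation. It cannot be told apart from an effect of activated Smoothened or of the induction of the allele, because 0 arrays held 4OHT-treated cells without the allele.

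The small response of hedgehog target genes is a second pattern. The 19 targets brighter than the median gene had a median log2 fold change of -0.15. Its upper 95% bootstrap bound was 0.000193, with genes and not wells resampled. The 9 dimmer targets, Gli1 and Hhip among them, had a median of 0.054. The 19 brighter targets were picked for lying away from the arrays' floor, so they cannot test compression of fold changes near it. Of these targets, 0 were called higher and 7 lower. For the 9 dimmer targets such compression stays open, since no detection calls were used. A general loss of cilium gene expression is argued against by the cilium list. Its mean log2 expression was 9.35 ± 0.04 in vehicle wells and 9.41 ± 0.01 in 4OHT wells (SD, n = 3). Its median had a lower 95% bound of -0.0111 when its genes were resampled, which measures the spread between genes and not between wells. With 17 members higher and 12 lower, the list does not decide whether single cilium genes fell. A small share of cells with the activated allele could give the same values and cannot be told apart from a weak response, because the Smo probe set, at a log2 fold change of -0.0983, is not known to read the transgene.

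Interferon-stimulated genes in vehicle replicate 1 make another pattern. Usp18, named after its values were seen, had a log2 expression of 10.03 there, against 8.34 and 8.44 in the other vehicle wells and 9.33 to 9.92 in 4OHT wells, and 21 of the 30 genes were at or above the lowest 4OHT array. A 4OHT well with a wrong label is argued against, because over 1569 other genes called without this array it lay at 0.0564 on a scale from vehicle (0) to 4OHT (1). Without this array 16 of these genes passed, against 3 with all arrays and at most 4 without any other array. Whether an interferon response in this well lessened the measured difference stays open, because that count uses the genes in which the high values were seen.

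The 6 arrays make 10 splits into groups of 3, too few for a share under 0.05. In 1 of the 10, the real one, 2662 genes were called, and the highest count in any other split was 0 by limma, where up to 965 genes had an unadjusted p under 0.05 against 5858 in the real split. For gene lists the real split gave 17, again reached by 1 split of 10, and the highest other gave 8. Every other split mixed vehicle and treated arrays in both of its groups. The treatment difference then added to the spread within groups and partly cancelled between them. The counts of the other splits therefore cannot show how many genes or lists would be called if the treatment had no effect.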
